A study of Perkinsus marinus with 6 samples.

How the data were processed

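Total RNA from 6 Perkinsus marinus cultures was sequenced after Illumina library preparation, per the labels' protocols, with 3 libraries from lipid-replete and 3 from lipid-deplete medium. Each library has 1 table of annotated genes. The deposited count column holds whole, unnormalized reads per gene, and per the file headers its sum equals the reads mapped to features. The deposited RPKM values divide that count by the whole gene span in kilobases, introns included, and by the library's total mapped reads, scaled as RPKM is defined, as recomputation from the file showed. The deposited fraction column gives the part of each gene's span covered by reads. The aligner, counter, genome build and strand setting are not given in the sources used here; the submitters' processing notes name DESeq with neither version nor role. Since strand use is unknown, reads of genes overlapping on opposite strands cannot be told apart, and reads matching several places, which are part of the mapped total, leave near-identical copies uncertain.

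The tables list 29473 features, 23474 protein-coding and 5999 tRNA, on 7623 contigs. All 29473 matched the RefSeq table of assembly JCVI_PMG_1.0 by identifier and by coordinates. That table gives every gene its locus tag as symbol and no product name. The 23 gene lists fixed by product-name patterns before the data were examined could therefore not be filled, and no list test or enrichment was run. The rule for named genes, fixed with them, then keeps the 2 largest rises and 2 largest falls among genes with an adjusted p under 0.05, no overlap of the groups and a mean CPM of at least 5.

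Total mapped reads were 86062448, 83354152 and 87004627 in lipid-replete A, B and D and 88314326, 89000257 and 76642117 in lipid-deplete A, B and D. At these depths 1 read equals 0.0154 CPM in the smallest library, and 3452 features had no read in any library. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 7.90 to 51.8 within groups), so all were kept.

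Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total count 15), TMM factors, which ranged from 0.921 to 1.08, and a robust quasi-likelihood fit with group as the only term. Adjusted p-values are Benjamini-Hochberg over 21138 genes at a threshold of 0.05. The common dispersion corresponded to a biological coefficient of variation of 8.29%. On simulated counts for these 21138 genes, with 200 changed, the fit recovered 40% of genes changed 1.25-fold, 56% at 1.5-fold, 84% at 2-fold and 98% at 4-fold. It called 0.0669% of unchanged genes. The data gave 8515 changed genes, and the Benjamini-Hochberg cutoff depends on the changed share, so these rates do not carry over to the data. CPM values use TMM-adjusted library sizes, but the reads summed over all tRNA features were scaled to unadjusted totals of reads in features. Classes of genes were tested with camera and fry from limma 3.58.1. Single measures per library were compared by exact permutation over 3 against 3 libraries. Adjacent genes on a contig were paired by distance and strand, and any overlapping spans counted as under 200 bp apart. There were 1000 bootstrap resamples, 10000 permutations of fold changes, and 1000 shuffles for runs. Intervals of shares cover counting error only. Figures were drawn with matplotlib 3.10.9.

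Alternatives fixed before the data were examined were DESeq2 size factors, library totals with and without the 10 most abundant genes, upper-quartile scaling, no or a stricter low-count filter (5 CPM in 3 libraries), the DESeq2 1.42.0 Wald test, limma-voom, the replicate letter as a block, omission of each library or letter, an adjusted p of 0.01, glmTreat at 1.5-fold, and limma on log2(RPKM + 1) and log2(RPKM + 0.1) of the deposited RPKM, with a minimum mean RPKM of 1 or none. Offsets from a lowess of log2 CPM on gene length were added after the data were seen. Corrections for GC content and for near-identical copies were not run, as no genome sequence was used here.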

Results

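RNA sequencing compared cultured cells of Perkinsus marinus, a single-celled alveolate parasite of the eastern oyster, grown with and without a lipid supplement. The labels give the purpose as measuring how withdrawal of lipids from the growth medium alters transcription. Log-phase cultures were set to an optical density of 0.1 at 600 nm, divided into lipid-replete medium with lipid concentrate at 1X and lipid-deplete medium with none, and harvested at day 11 from growth at 27 °C. Each group holds 3 libraries, called A, B and D, which the labels describe as biological replicates. Reads assigned to annotated genes came to 73478472, 71614956 and 74660460 in lipid-replete A, B and D and to 74589368, 75060399 and 64728778 in lipid-deplete A, B and D. The strain entry ends in a different number in each of the 6 libraries, whereas the growth protocol names 1 clonal isolate. Libraries of a group resembled each other more than libraries of different groups. Across genes, Pearson's r of log2 CPM (counts scaled to a common library total) was 0.992 to 0.994 within groups and 0.981 to 0.984 between them, and the first principal component, with 56.0% of the variance, placed the 3 lipid-replete libraries at −35.5 to −28.4 and the 3 lipid-deplete libraries at 32.7 to 33.2.

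Lipid withdrawal was accompanied by changes in a large part of the transcriptome, most of them small. Of 21138 tested genes, 8515 (40.3%) differed between the groups at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), with 4494 higher and 4021 lower in lipid-deplete cells. The median change among these genes was 1.36-fold, and 5716 of them (67.1%) changed by less than 1.5-fold. Only 813 changed at least 2-fold, 371 of them higher and 442 lower. In 10627 genes (50.3%) the 3 libraries of one group all lay above the 3 of the other, against 10% by chance. The split between directions depended on the scaling: genes that rose were 52.8% of the changed genes with TMM factors and 72.5% with library totals alone, which moved the median of all genes by 0.12 on the log2 scale, so changes are given relative to the TMM scale.

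**Figure D1:**
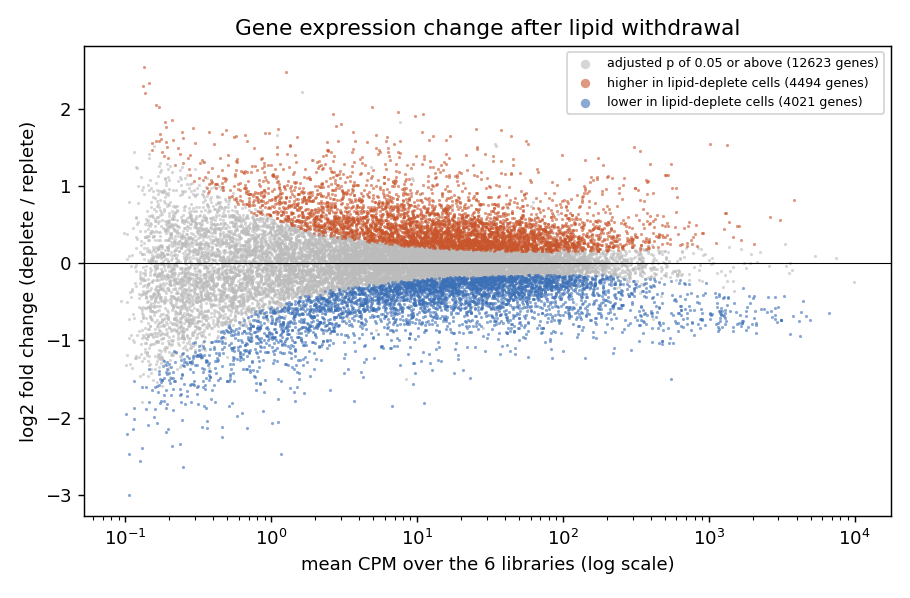
Log2 fold change (lipid-deplete over lipid-replete) against mean CPM on a log axis, 1 point per tested gene. The 4494 genes that rose are orange, the 4021 that fell are blue and the others grey; at the highest abundances the blue points outnumber the orange ones.

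The files and the reference table pair the gene identifiers with no product names, so genes are given by identifier and position on assembly JCVI_PMG_1.0. All 4 genes named by the rule are annotated as protein-coding on the minus strand. Among genes with a mean CPM of at least 5 and no overlap between the groups, Pmar_PMAR015417 (NW_003216106.1, 44026 to 44584) rose most, from 3.02 ± 0.351 to 11.8 ± 1.04 CPM (SD, n = 3), a log2 fold change of 1.96 (SE 0.11, edgeR adjusted p = 1.26e-08). Pmar_PMAR015524 (NW_003203827.1, 19023 to 20117) rose from 4.53 ± 0.502 to 17.3 ± 0.887 CPM, by 1.93 on the log2 scale (SE 0.094, edgeR adjusted p = 5.19e-09). The deepest falls were in Pmar_PMAR010274 (NW_003217015.1, 782251 to 782454), from 10.6 ± 0.742 to 2.94 ± 0.188 CPM and a log2 fold change of −1.85 (SE 0.10, edgeR adjusted p = 1.18e-08), and in Pmar_PMAR020148 (NW_003203299.1, 230 to 1352), from 17.4 ± 0.366 to 4.96 ± 0.358 CPM and a log2 fold change of −1.81 (SE 0.083, edgeR adjusted p = 4.11e-09). The gene with the largest rise lay in a stretch of 5 neighbouring genes (NW_003216106.1, 35823 to 47273) that were all higher in lipid-deplete cells. Their mean log2 fold change was 0.75, which includes the 1.96 of that gene, and the lowest was 0.20. Without lipid-deplete A, 4 of the 5 passed.

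**Figure D2:**
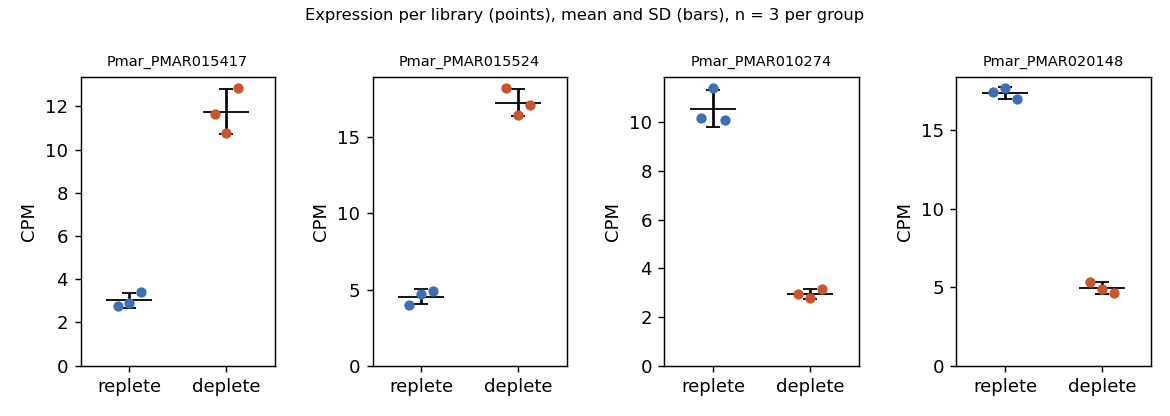
CPM of the 4 named genes in each library (points), with the group mean (horizontal line) and SD (bars), n = 3 per group. In each panel the 3 libraries of one group lie apart from the 3 of the other, as in Pmar_PMAR015417 with means of 3.02 and 11.8 CPM.

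Most of the short genes among the most abundant transcripts were lower in lipid-deplete cells. As a class they shifted downward only in camera with a preset correlation of 0.01 (adjusted p = 1.72e-13), and not with an estimated one (adjusted p = 0.43 with an estimated correlation) or in fry (adjusted p = 0.0616). The classes by abundance and gene span (introns included) were formed after the values were seen. Of the 75 genes under 1000 bp among the 100 most abundant, 59 were lower in lipid-deplete cells, 9 were higher and 7 did not pass, with a median log2 fold change of −0.63 and an interquartile range of −0.75 to −0.43. Adjusted over the list alone, 62 were lower and 9 higher. Their median expression was 2255 ± 329 CPM in lipid-replete and 1603 ± 90.1 CPM in lipid-deplete libraries (SD, n = 3), and each lipid-deplete library (1500 to 1665) lay below each lipid-replete library. Lipid-replete A, at 1876 CPM, stood nearer to the lipid-deplete libraries than lipid-replete B and D, at 2427 and 2463 CPM, and its TMM factor was 1.03 against 0.932 and 0.921. Of the 25 longer genes among the 100, 4 were higher, 5 lower and 16 did not pass, with a median log2 fold change of 0.0046, and with library totals alone 9 were higher and 4 lower. Counts split in a like way among the next genes, down to abundance rank 300, where 80 of 104 short genes were lower and 12 higher (median −0.62). Of 96 longer genes there, 17 were lower and 28 higher (median 0.018). From there to rank 1000 the medians of short and longer genes lay closer, with 95 of 196 short genes lower and 42 higher (median −0.22). Of 504 longer genes there, 99 were lower and 157 higher (median 0.020). No set test was run past rank 100, and differences between rank ranges were not tested. With library totals alone the medians of these 3 short classes were −0.50, −0.49 and −0.10, and in the last of them 79 genes were then lower and 52 higher.

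As a share of all reads in genes, the 100 most abundant genes took 25.9% ± 1.83 in lipid-replete and 22% ± 0.734 in lipid-deplete libraries (SD, n = 3), a difference of −3.90 percentage points. Their short members accounted for it, with 19.9% ± 2.0 (17.7% in lipid-replete A, 20.5% in B and 21.5% in D) against 15.6% ± 0.691, while the longer members took 6.01% ± 0.213 against 6.37% ± 0.0483. Each of these differences had a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.183 over 11 measures). Measures of the libraries moved with the same groups: reads outside annotated features were 14.3% ± 0.286 of mapped reads in lipid-replete and 15.6% ± 0.0694 in lipid-deplete libraries, and the covered part of 2548 genes that changed little was 91.8% ± 0.959 and 89.0% ± 1.01, with all 3 libraries of each group apart (SD, n = 3; exact p = 0.1 for each).

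**Figure D3:**
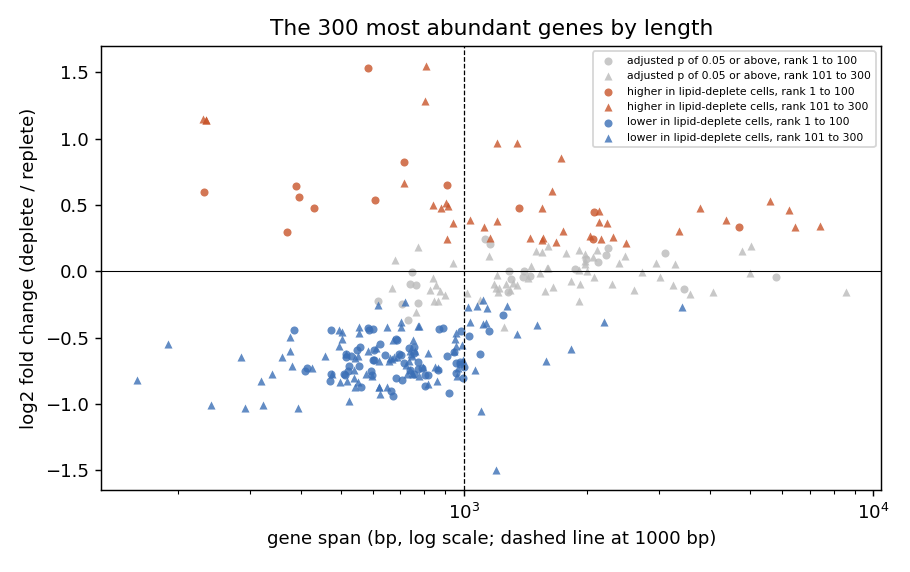
Log2 fold change (lipid-deplete over lipid-replete) against gene span in bp on a log axis for the 300 most abundant genes; circles are ranks 1 to 100, triangles the next genes down to rank 300, and colours give the test result. Blue points (lower) gather left of the dashed line at 1000 bp, with 59 of 75 circles there.

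Genes that lie close to each other on the same strand tended to change together. This relation and the regions below were also chosen after the values were seen. Across 2240 pairs of adjacent genes on the same strand under 200 bp apart, the log2 fold changes of the partners correlated with Pearson's r of 0.318 (95% bootstrap interval 0.266 to 0.372, Spearman's rho 0.311, permutation p = 1e-04, the smallest that 10000 permutations give, adjusted p = 0.000233 over 14 relations). The correlation was 0.253 from 200 to under 500 bp, 0.154 from 500 to under 1000 bp, 0.176 from 1000 to under 3000 bp and −0.0012 over 978 pairs at 3000 bp or more (permutation p = 0.971). Over all distances r was 0.194 for 9561 same-strand pairs and 0.0673 for 5390 pairs on opposite strands, a difference of 0.126 (permutation p = 1e-04). Shuffling the strand classes within distance bins gave a mean difference of 0.0371, the part that goes with distance alone. On opposite strands r was 0.148 under 200 bp (adjusted p = 0.007), 0.0818 from 200 to under 500 bp, 0.0681 from 500 to under 1000 bp and 0.0246 from 1000 to under 3000 bp. At 3000 bp or more it was 0.108 (adjusted p = 0.0021), above the same-strand value, a difference that was not tested. These correlations run across genes, which are not independent replicates. Where both partners passed the test, they moved in the same direction in 316 of 447 same-strand pairs under 200 bp apart (70.7%, exact Clopper-Pearson 95% interval 66.2 to 74.9), 173 of them higher and 143 lower. At 3000 bp or more it was 100 of 201 pairs (49.8%, 42.6 to 56.9; Fisher's exact test, p = 3.96e-07). That test treats pairs as independent, although adjacent pairs can share a gene and all fold changes come from the same libraries. Other distances and pairs on opposite strands were not compared in this way.

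**Figure D4:**
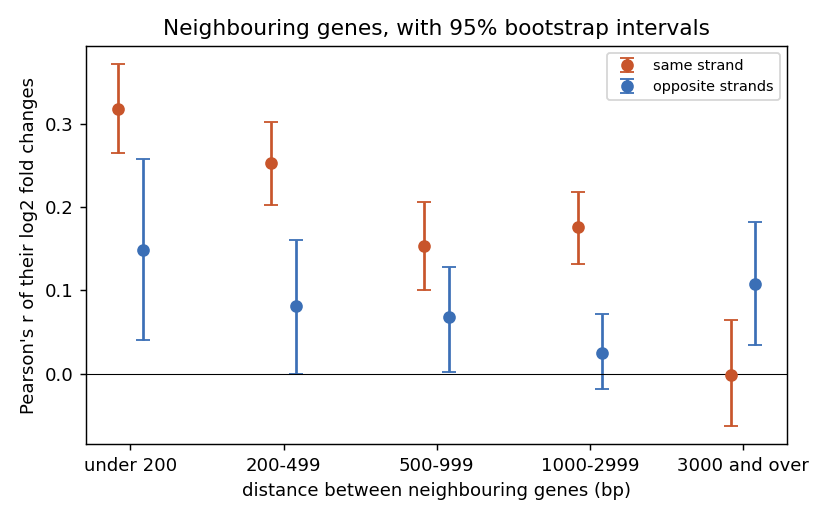
Pearson's r between the log2 fold changes of adjacent genes, by the distance between them in bp, for genes on the same strand (orange) and on opposite strands (blue), with 95% bootstrap intervals. Same-strand values are 0.318 under 200 bp and −0.0012 at 3000 bp or more, where the opposite-strand value of 0.108 lies above them.

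Some contigs carried longer stretches of genes that moved in one direction. There were 37 runs of 5 or more consecutive tested genes that changed in the same direction, 21 higher and 16 lower, against a mean of 10.9 and a maximum of 21 when fold changes were shuffled among positions 1000 times (permutation p = 0.001, the smallest possible). In the longest, all 10 genes of a minus-strand stretch on NW_003213081.1 (2722 to 42514) were lower, with log2 fold changes from −1.02 to −0.46 and a mean of −0.68. The longest run in shuffled data had 6.46 genes on average and 12 at most (permutation p = 0.00999), so shuffling could give a longer run. Calls were also more frequent among abundant genes, with 77% changed at ranks 1 to 100 and 30.6% below rank 10000. Whether genes of like abundance lie together on contigs, and so add to the runs, was not tested. On NW_003216064.1 (234441 to 249427) 6 genes were higher with a mean log2 fold change of 0.80, and on NW_003212444.1 (32378 to 39896) 5 genes were lower with a mean of −0.96. The weakest gene had 0.890 CPM in the former and 0.593 CPM in the latter, and 0.469 CPM in the longest run. Runs of 3 genes that each changed at least 2-fold numbered 7, against 0.239 on average when shuffled. Of these the most abundant was a run of 3 higher genes on NW_003213929.1 (94486 to 105557), with a mean log2 fold change of 1.10 and at least 155 CPM per gene. Genes of the run on NW_003209596.1 had at least 110 CPM. In each of the other runs of 2-fold changes the weakest gene was low, at 0.143 to 0.933 CPM.

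The number of runs, and of genes passing in a run, varied with the libraries used. The 37 runs became 46 without lipid-replete A, 18 without lipid-replete B, 22 without lipid-replete D, 15 without lipid-deplete A, 19 without lipid-deplete B and 19 without lipid-deplete D. All changed genes moved the same way, from 8515 to 9018 without lipid-replete A and to 6709 to 7301 without any other library. The counts of runs therefore do not show that single libraries drive them. In the longest run 5 of the 10 genes passed without lipid-deplete A, and 5 with library totals alone. In 10 of the 37 runs, among them the runs named above on NW_003216064.1 and NW_003212444.1, and in 2 of the 7 runs of 2-fold changes, among them that on NW_003213929.1, every gene passed in each of the 6 fits without 1 library. On NW_003200421.1 (3083 to 4470) 1 of the 3 genes changed 2-fold passed without lipid-replete A, and 1 with library totals alone.

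**Figure D5:**
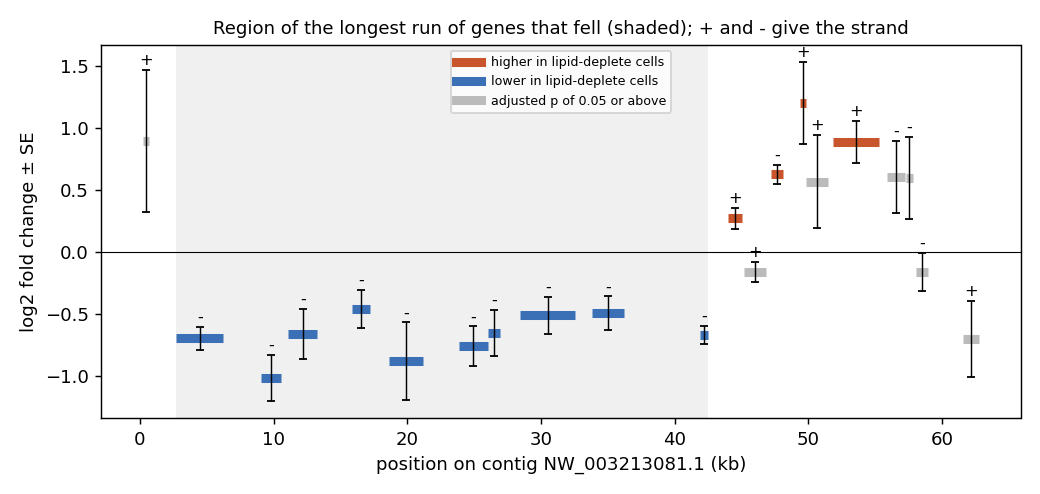
Log2 fold change with SE for the genes at the start of contig NW_003213081.1, each drawn as a bar over its span in kb with its strand sign; shading marks the longest run. The 10 shaded minus-strand genes lie between −1.02 and −0.46.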

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

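The tests on coverage, tRNA features and reads outside genes were chosen after the results were seen, and groups of 3 libraries were not searched for outlying samples.

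Reads outside the annotated features made up 14.3% ± 0.286 of mapped reads in lipid-replete and 15.6% ± 0.0694 in lipid-deplete libraries (SD, n = 3), a difference of 1.28 percentage points in reads that no comparison used; all 3 lipid-deplete libraries lay above all 3 lipid-replete ones (2-sided exact permutation p = 0.1, the smallest possible; adjusted p = 0.183 over 11 measures). Among the tRNA features, nearly all left out of the test by the count filter, 1017 ± 125 had a read in lipid-replete and 1214 ± 37.4 in lipid-deplete libraries, a difference of 197 (exact p = 0.1, adjusted p = 0.183). Reads in tRNA features were 82.1 ± 5.64 and 83.0 ± 2.88 CPM, taken over all reads in features without TMM factors (exact p = 0.9, adjusted p = 0.9). The sum was not tested on the TMM scale.

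Genes were covered over less of their span in lipid-deplete libraries: over 2548 genes longer than 1000 bp with at least 1000 reads in each library and a log2 fold change within 0.15 of 0, the covered part was 91.8% ± 0.959 in lipid-replete and 89.0% ± 1.01 in lipid-deplete libraries (exact permutation p = 0.1, the smallest possible; adjusted p = 0.183). Sequencing depth is argued against by 1229 genes with more reads in lipid-deplete A and B than in every lipid-replete library, which were still covered less there, with a difference of −2.33 percentage points against an SD of 0.721 among lipid-replete libraries. Genomic DNA in the lipid-replete libraries may raise coverage of introns, but it would also add reads outside annotated features. That share of mapped reads was lower in lipid-replete (14.3% ± 0.286) than in lipid-deplete libraries (15.6% ± 0.0694), without overlap. Genomic DNA alone would give the opposite direction. The share also depends on how many reads transcripts place inside and outside annotated features, so a small input of genomic DNA stays open. The count of tRNA features with a read does not decide it either. The lowest lipid-deplete library had 26 more of them than the highest lipid-replete library, within the SD of 125. Fewer distinct fragments in the lipid-deplete libraries stay open, since the number of protein-coding genes with a read differed by only −42 on average between groups whose ranges overlapped. A change in splicing or transcript ends after lipid withdrawal is a further open explanation that was not tested.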

How the results depend on the processing

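The classes of abundant short genes, the neighbour relation, the runs and the length offsets were chosen after the results were seen. The 4 named genes kept their direction and passed in each of 25 alternatives, with log2 fold changes of 1.85 to 2.08, 1.76 to 2.06, −1.92 to −1.67 and −1.86 to −1.49 and a largest adjusted p of 5.08e-05. The neighbour correlation under 200 bp stayed between 0.25 and 0.376. Library totals gave 2254 lower genes and 57 runs, and 2447 lower without the 10 most abundant genes; the limma fits on RPKM, also scaled to totals, gave 2125 lower and 260 changed 2-fold (pseudocount 1), 2111 and 488 (0.1), and 2082, 261 and 20 runs (no filter). The cause of these was not tested beyond the shift of 0.12 in the median. A stricter filter left 230 genes changed 2-fold, with fewer genes tested. An adjusted p of 0.01 gave 5667 changed genes, 2559 lower and 10 runs. Tested against 1.5-fold with glmTreat, 565 passed, 367 higher and 198 lower, 389 of them changed 2-fold, with 0 abundant short genes lower and 1 higher, and 0 runs; 24 abundant short genes were lower at an unadjusted p under 0.05 there, and against no change 59 were lower with edgeR and 62 with DESeq2. Their set test gave an adjusted p of 0.43 with an estimated correlation and 0.0616 with fry.

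Without 1 library or 1 letter, changed genes numbered 5502 to 9018, lower genes 2417 to 4274, lower abundant short genes 37 to 63 and runs 6 to 46, each lowest without letter B, which leaves 4 libraries. Without 1 library, 77.1% to 91.7% of the 8515 calls were kept and none reversed, and 5591 were kept in all 6 fits. The share of the 100 most abundant genes differed by −4.94 to −3.21 points. The labels do not say whether a letter marks a shared starting culture. Deviations from the group mean correlated by −0.0245 (A), −0.0781 (B) and 0.0364 (D), with the best match to the own letter only for D. Such values show little shared deviation and leave a shared culture open. The replicate block called 8180 genes. Only 10 splits of 3 against 3 libraries exist, too few for a share under 0.05. The real split alone reached 8515 genes. The highest other called 0 with edgeR (at most 922 at an unadjusted p under 0.05), 4 with DESeq2 and 0 with limma-voom. Each other split mixes libraries of both groups, so the group difference adds to the spread within its sides. Few calls follow from that mixing, and these counts do not measure false calls. Depth limits changes of low genes, since 1 read is 0.0154 CPM. List tests, GC correction and removal of near-identical copies were not run.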

Other observations

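The tests on tRNA features, gene length, library scaling and single libraries were chosen after the results were seen, as were the patterns; those on neighbouring genes had been set before their results.

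Of the 102 tRNA features with enough reads to be tested, 14 were lower in lipid-deplete cells, 2 were higher and 86 did not pass, with a median log2 fold change of −0.30 (edgeR, Benjamini-Hochberg). With library totals alone 11 were lower and 5 higher (median −0.18), and with limma on log2(RPKM + 1) 20 were lower and 9 higher (median −0.16); without lipid-replete A the median was −0.19. Adjusted over the class alone, 9 were lower and 0 higher with edgeR (20 and 5 at an unadjusted p under 0.05), and 0 were higher with DESeq2 or limma-voom. Reads over all tRNA features, tested or not, were scaled to all reads in features without TMM factors. On that scale they did not fall detectably (exact permutation p = 0.9). They were 82.1 ± 5.64 CPM in lipid-replete and 83.0 ± 2.88 CPM in lipid-deplete libraries (SD, n = 3). The TMM factors were 0.960 ± 0.0579 in lipid-replete and 1.04 ± 0.0309 in lipid-deplete libraries (SD, n = 3). The sum was not tested on the TMM scale, so it cannot be set against the median of −0.30. The tested features moved downward in fry (adjusted p = 0.000261) and in camera with the preset correlation (adjusted p = 0.0499), though not with an estimated one (adjusted p = 0.118 with an estimated correlation). Their counts were low, with a median of 0.283 CPM. The number lower was 7 without lipid-replete B, and 9 without lipid-replete D, lipid-deplete A or lipid-deplete B. It was 4 without letter B, 7 at an adjusted p of 0.01 and 2 with glmTreat at 1.5-fold, but 15 without lipid-replete A and with the replicate block. The stricter filter of 5 CPM left no tRNA feature to test.

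Further runs of genes that moved together were seen on 3 contigs, chosen after their values were known. On NW_003203798.1 (35434 to 60970) 8 genes were higher with a mean log2 fold change of 0.44, of which 5 passed without lipid-replete B. On NW_003204277.1 (234966 to 255751) 8 genes were higher with a mean of 0.35, of which 5 passed without lipid-deplete D. On NW_003209596.1 (128033 to 139840) 3 abundant genes were all raised at least 2-fold, with a mean log2 fold change of 1.11, and 1 of them passed without lipid-replete A. Changes of at least 2-fold lay mostly in weakly expressed genes: of the 11138 tested genes below abundance rank 10000, 268 were at least 2-fold higher and 396 at least 2-fold lower.

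The lower levels of most abundant short genes were set against 3 technical explanations. A bias against short genes in lipid-deplete libraries would also lower less abundant short genes, but past rank 1000 and down to rank 10000 short genes moved against long ones by only −0.041 between the groups (log2 scale, per library; larger group SD 0.056). A factor common to all genes of a library cancels in the gap between short and long genes among the 100 most abundant, which was lower in each lipid-deplete library and differed by −0.65 (larger group SD 0.24); these classes were chosen on the same libraries, and the gap shows unequal change, not absolute levels. At least 57 of the 75 genes were still lower in each fit without 1 library, against the 59 with all 6. A response of the class to lipid withdrawal remains a hypothesis, since its set test did not pass with an estimated correlation (adjusted p = 0.43 with an estimated correlation) or in fry (adjusted p = 0.0616), and the identity of the genes was not tested; the lower coverage and larger share of reads outside features in lipid-deplete libraries go with the same groups, so an effect of RNA or library quality stays open too.

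Technical explanations were also set against the shared change of neighbouring same-strand genes. Reads running from an abundant gene into its neighbour would leave little correlation between partners of similar abundance, yet r was 0.403 over 1296 such pairs under 500 bp apart (bootstrap SD 0.034), above the 0.289 over all 4115 pairs. Without pairs of matching length, which adjacent copies would form, r was 0.285 (SD 0.018), and after removal of the median of each abundance and length class it was 0.290 (SD 0.019). A single transcript annotated as several genes, reads shared between copies of unequal length and a shared control of transcription stay open, and none of them was tested. Pairs that converge on opposite strands under 200 bp apart had r of 0.267 (164 pairs) and divergent pairs 0.0608 (214 pairs), a difference that was not tested. Any overlapping genes are among the pairs under 200 bp apart on either strand, and an effect of overlap was not tested.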
